A study of Danio rerio with 54 samples.

How the data were processed

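Embryos of the wildtype AB strain and of an nfe2 knockout line were dosed with water, 20 µM diquat or 1 mM tBOOH for 4 h from 2, 48 or 96 hpf and recovered for 4 h, in pools of 30, with 3 pools in each of 18 groups. The knockout was made with TALENs that left an 8-base deletion in exon 3. Per the submitters' processing notes, directional poly(A) libraries were read as 50 bp pairs, checked with FastQC 0.11.4, aligned with TopHat2 2.0.14 and Bowtie2 2.2.5 to GRCz10, handled with SAMtools 0.1.19, counted per gene with HTSeq and normalised with DESeq2 1.10.1 in R 3.2.3. The HTSeq version and its strand setting are not given in the sources used here, nor is the way in which reads of overlapping genes or paralogs were assigned.

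The deposited table gives a signal for each of 31953 genes and 54 libraries: gene counts divided by 1 size factor per library, as made by the authors. In each column every value (100%, within 0.01 read) was a whole multiple of 1 step, so the whole reads behind it were recovered; in 3 columns the size factor lay so near 1 that this check decides little. Size factors ran from 0.571 to 1.42. The recovered reads had a median of 0.772 M, 3.09% of the 25 M reads per sample that the study stated, which limits the precision for genes of low level. Counting error alone sets the floors: a group of 3 libraries without a read was given 3 reads over the group as its upper bound. Gene symbols came from the deposited table. A separate table of gene names, which held 26121 of its IDs, served to match the gene lists. Of the IDs in the data 3981 shared a symbol with another ID and carry their ID here, 50 had no symbol, and names with "(1 to many)" are printed as the source gives them, so reads of close paralogs may be mixed. The location of nfe2 is from GRCz12tu, while the counts rest on GRCz10.

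Within each stage a linear model on log2(value + 1) was fitted to the 18 libraries of 6 groups with limma 3.58.1 (empirical Bayes with a mean trend) in R 4.3.3, for genes with a value of 10 or more in at least 3 libraries: 7783, 9725 and 11436 genes at 2, 48 and 96 hpf. Contrasts were each oxidant against water in each genotype, knockout against wildtype in water, the genotype difference in each response (interaction), and tBOOH against diquat in wildtype. A fit of all 54 libraries (13205 genes) gave the stage differences of the wildtype responses (F test) and the change between stages in wildtype water. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. Where a comparison rests on 3 libraries a group, replicate numbers were checked as pairs. After group means were removed, libraries with the same number had a mean correlation of 0.0377, -0.00964 and -0.000254 at 2, 48 and 96 hpf. Libraries with other numbers had -0.0189, 0.00486 and 0.000309. Of 18 libraries a stage, 11, 4 and 8 went best with their own number. Pairing is therefore not excluded at 2 hpf. The main fit leaves it out, and the replicate number as a block is an alternative.

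Comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. There were 35 lists with 1295 genes, of which 1245 were matched: CNC family and partners, Nrf2-type antioxidant genes, glutathione enzymes, peroxide and superoxide enzymes, heat shock proteins, p53 targets, unfolded protein and integrated stress response, immediate early genes, inflammation, erythroid genes, thrombocyte genes, neutrophil and macrophage genes, proteasome subunits, iron and heme handling, aryl hydrocarbon receptor targets, hypoxia and glycolysis, cholesterol synthesis, cell cycle, circadian and light genes, maternal transcripts, gastrula and early segmentation genes, hatching gland, skeletal muscle, heart, lens crystallins, photoreceptors, liver, exocrine pancreas, intestine, epidermis, neurons, glia, vascular endothelium, mitochondrial transcripts and cytosolic ribosomal proteins. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list and with fry. For changes between stages only counts are given. Counts "adjusted over the list alone" adjust p over the members of that list.

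Named genes are nfe2 throughout; in each contrast the 8 largest rises and 8 largest falls (5 each for interactions and tBOOH against diquat) among calls with a mean of at least 50 in the higher group, all 3 libraries of one group beyond all 3 of the other (not asked of interactions) and a symbol that is not a clone name; up to 4 called members of each list with the smallest p; the CNC family in water; and, for stage differences, genes already named in the wildtype contrasts. Some genes the rule takes are left out, and genes named outside it are marked as chosen after their values were seen.

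Alternatives were a pseudocount of 5, no low-value filter, TMM rescaling, the replicate number as a block, only the compared groups in the fit, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. After the data were seen, a fit without the 3 libraries under 0.65 M reads and a fit with library quality weights were added. Simulated genes were raised or lowered 2-fold or 4-fold. Of these limma called 29% and 95% at 96 hpf, edgeR 38% and 94%, and DESeq2 23% and 86%. At 2 hpf limma called 52% and 88%, and at 48 hpf 33% and 90%. The interaction test called 11% and 64% at 96 hpf. Overlaps of calls were set against independence, and with the correlations and covariances of the responses against 20 simulations with shared controls. Files and figures were handled with Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9. Read sequences were not analysed here.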

Results

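Poly(A) RNA was sequenced from pools of 30 zebrafish embryos in 54 libraries, 3 for each of 18 groups. The groups crossed the wildtype AB strain with a germline nfe2 knockout, water with diquat at 20 µM and tert-butyl hydroperoxide (tBOOH) at 1 mM, and dosing from 2, 48 or 96 hours post fertilisation (hpf). Diquat is a redox-cycling herbicide and tBOOH an organic peroxide, and dosing lasted 4 h with 4 h of recovery. Groups are named here by the start of dosing: the treatment protocol has embryos frozen 8 h later, about 10 hpf for the first stage, while the sample description gives 2, 48 and 96 hpf as the sampling times. The knockout line carried AB and TL ancestry and the wildtype was AB, so genotype and background differed together. The table held 31953 genes. Whole read counts recovered from it summed to between 0.527 and 1.04 M per library (median 0.772 M), with 0.740 to 1.04 M at 2 hpf, 0.527 to 0.876 M at 48 hpf and 0.533 to 0.862 M at 96 hpf. In each of the 54 libraries mt-nd6, the light-strand gene among the 13 mitochondrial mRNAs, stood above the median of the other 12, and in 44 it was the highest. The strand setting of the counting is not given, so whether the values here count sense or opposite-strand reads stays open. Values below are normalised read counts as mean ± SD of 3 libraries, and log2 changes ± SE with adjusted p from limma. The p-values measure spread between pools of embryos, estimated jointly over the 6 groups of a stage. Groups differed in spread. The chi-square per gene between libraries of a group ran from 1.26 (96 hpf wildtype water) to 14.3 (48 hpf knockout tBOOH). With only the compared groups in the fit, several wildtype oxidant counts rose and several knockout ones fell, as given below. Counts of calls are therefore not a like measure between the genotypes. Each gene named for a large change between groups had all 3 libraries of one group above all 3 of the other, an arrangement that chance gives 10% of the time.

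The mutated gene, nfe2 (ENSDARG00000020606, chromosome 23 from 39416601 to 39445468 in GRCz12tu), encodes a transcription factor of the CNC family, which binds antioxidant response elements. Its mRNA was measurable in the 2 hpf series, at 11.6 ± 7.24 in wildtype water and 16.51 ± 6.48 in knockout water (log2 difference 0.56 ± 0.47, adjusted p = 0.383). The 2 hpf means were 5.47 ± 3.37 and 8.87 ± 2.94 in wildtype diquat and tBOOH, and 20.2 ± 13.3 and 19.9 ± 2.11 in knockout diquat and tBOOH; no contrast of nfe2 passed the test. No group mean exceeded 1.93 at the later stages. In wildtype water at 48 hpf none of the 3 libraries held an nfe2 read, which allows a mean of up to 0.975 at this depth (such floors cover counting error only), and nfe2 was too low there to be tested. The 8-base deletion shifts the reading frame and does not remove the transcript, so these levels check neither the genotype nor the protein. Among relatives, nfe2l2a (the Nrf2 gene) rose in wildtype water from 1.08 ± 0.464 at 2 hpf to 33.0 ± 12.8 at 48 hpf and 83.2 ± 9.03 at 96 hpf, with adjusted p of 1.48e-11 and 0.0106 for the steps. The level of nfe2l3 was 57.0 ± 9.02, 55.9 ± 1.89 and 34.7 ± 8.88 at the same stages, and its fall from 48 to 96 hpf passed the test (adjusted p = 0.0104). At 96 hpf nfe2l2a was lower in knockout than in wildtype water (44.0 ± 7.25 against 83.2 ± 9.03, log2 change -0.91 ± 0.20, adjusted p = 0.0015), as was bach1b, a repressor of the same elements (7.86 ± 4.18 against 15.2 ± 3.24, adjusted p = 0.0362). The call of bach1b ended without wildtype water replicate 1 or 2 or knockout water replicate 1 or 3 (adjusted p up to 0.211).

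In wildtype water, the passage from the 2 hpf to the 48 hpf series brought up muscle, lens and nerve. Of 38 skeletal muscle genes 37 rose (median log2 7.33), as did 33 of 36 lens crystallins, 35 of 40 neuronal, 22 of 28 erythroid and 10 of 15 vascular endothelium genes. Gastrula and early segmentation genes fell in 36 of 47 cases (median log2 -2.59, or -2.62 with genes at 0 in one stage set to their bound), and cell cycle genes in 27 of 41. Between 48 and 96 hpf the digestive organs and retina came up: all 16 exocrine pancreas genes, 20 of 21 intestine, 39 of 44 liver and 38 of 41 photoreceptor genes rose, with median log2 changes of 5.19, 4.27, 3.61 and 4.11. Antioxidant genes joined them, with rises in 16 of 21 Nrf2-type and 13 of 19 glutathione genes, while 24 of 41 cell cycle and 22 of 40 proteasome genes fell. Other lists were mixed or moved less: in the first step 21 of 34 circadian and light genes rose and 1 fell (21 and 1 adjusted over the list alone), 6 of 8 thrombocyte genes rose and 2 fell (6 and 2), 5 of 10 maternal transcripts fell and 1 rose (5 and 1), 3 of 7 hatching gland genes rose and 2 fell (3 and 2), and 7 of 17 peroxide and superoxide genes rose and 1 fell (7 and 1). In the next step 5 of 15 neutrophil and macrophage genes rose (5), as did 7 of 14 cholesterol synthesis genes (8), and 2 of 12 CNC family and partner genes rose and 2 fell (2 and 2). For the lists named before these, the counts adjusted over the list alone were 37, 33, 35, 22, 10, 37 and 28 for the first step, and 16, 20, 40, 38, 16, 14, 24 and 30 for the next, in the order given. In all, 5051 genes rose and 2661 fell from 2 to 48 hpf, and 2607 rose and 1096 fell from 48 to 96 hpf, of 13205 tested. The median gene rose by 0.39 in the first step (0.0058 without the low-value filter, 0.25 with a pseudocount of 5) and by 0.20 in the next (0.084 with TMM rescaling), so single log2 values are relative to these shifts.

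Diquat given from 2 hpf moved few wildtype genes, and most of those called fell. The retinoic acid hydroxylase gene cyp26c1 (ENSDARG00000097644), the melanin-concentrating hormone receptor gene mchr1b and the amyloid precursor gene appb (ENSDARG00000097336) rose, mchr1b from 195 ± 24.6 to 465 ± 42.2 (log2 change 1.25 ± 0.18, adjusted p = 0.000186). The diacylglycerol kinase gene dgkb fell from 183 ± 54.8 to 38.8 ± 5.87 (log2 change -2.18 ± 0.32, adjusted p = 0.000232), and the amino acid transporter gene slc7a8a (-1.37 ± 0.29) and ttc14 (-1.58 ± 0.26) fell with it. Of 22 heat shock genes 1 rose, hsp90aa1.1 (1.33), and of 11 p53 targets 1 rose, ccng1 (0.75), with 1 rise and 1 fall and with 1 rise adjusted over the list alone. The unfolded protein list stood higher as a set (median log2 0.39, camera adjusted p = 0.000675, and adjusted p = 0.016 with an estimated correlation). Its single call was the fall of dnajb9b (ENSDARG00000016886), an endoplasmic reticulum cochaperone, while 10 members rose and 1 fell adjusted over the list alone. Cytosolic ribosomal protein genes were also higher as a set (median 0.27, adjusted p = 1.9e-19; adjusted p = 0.23 with an estimated correlation), with 0 of 76 called and 6 adjusted over the list alone. Of the wildtype calls 7 were genes that also differed between the strains in water at 48 and 96 hpf, where independence gives 0.789, among them mchr1b, ttc14, dnajb9b and cacna1ha (ENSDARG00000097913). For these a difference between the pools other than diquat stays open. It stays open for dgkb too, which had no read in 2 hpf knockout water, at least 220.5-fold below wildtype water. In total 28 genes rose and 47 fell. The total was 48 and 35 without diquat replicate 2 and 3 in turn. It was 30, 38 and 41 without water replicate 1, 2 and 3 in turn. The call of cyp26c1 ended without diquat replicate 1 or 3 or water replicate 1, 2 or 3 (adjusted p up to 0.192). The call of slc7a8a ended without diquat replicate 2 or 3 or water replicate 1 (adjusted p up to 0.175). The call of hsp90aa1.1 ended without diquat replicate 3 or water replicate 1 or 2 (adjusted p up to 0.101). The call of ccng1 ended without diquat replicate 2 or 3 or water replicate 1 or 2 (adjusted p up to 0.27).

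The peroxide tBOOH given from 2 hpf raised SEL1L3 (1.87 ± 0.38), the superoxide-producing oxidase gene nox1 (1.27 ± 0.36), the lysosomal mannosidase gene man2b1 (1.04 ± 0.21) and serpinc1, which encodes antithrombin (1.03 ± 0.21). The heme oxygenase gene hmox1a was the 1 member called of 14 Nrf2-type genes and of 8 iron and heme genes, rising from 89.8 ± 22.6 to 164 ± 11.7 (adjusted p = 0.0247). The nuclear receptor gene nr6a1a (ENSDARG00000101508, -2.56 ± 0.56), kank4 (-1.83 ± 0.37), arhgap11a (ENSDARG00000098717, -1.73 ± 0.29) and the replication helicase gene mcm2 (-1.16 ± 0.22) fell. Cell cycle genes were lower as a set (median -0.23, adjusted p = 0.0014; adjusted p = 0.532 with an estimated correlation), with 1 of 40 called and 1 adjusted over the list alone. The 13 mitochondrial transcripts were higher as a set (median 0.44, adjusted p = 0.000200; adjusted p = 0.639 with an estimated correlation), though 0 were called by limma. Against diquat directly, tBOOH left dgkb (1.93), ttc14 (1.81), dock8 (1.74) and the gamma-glutamylcyclotransferase gene ggcta (1.77) higher, and nr6a1a (-2.47) and sox9b, from the aryl hydrocarbon receptor list (-2.46), lower. Of these ttc14 and ggcta are among the wildtype diquat calls that also differed between the strains, for which a pool difference stays open. Such a difference stays open for dgkb as well, which had no read in 2 hpf knockout water. In tBOOH against water 114 genes rose and 106 fell. That total was 640, 2 and 0 without tBOOH replicate 1, 2 and 3 in turn. It was 0 without water replicate 1 or 2. Each call named here for that contrast therefore ended without at least 1 of these libraries. Between the oxidants 250 genes were higher and 196 lower in tBOOH. Their number was 146, 223 and 257 without diquat replicate 1, 2 and 3 in turn. It was 718, 142 and 110 without tBOOH replicate 1, 2 and 3 in turn. The call of nr6a1a ended without diquat replicate 1 or tBOOH replicate 2 or 3 (adjusted p up to 0.104).

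In the knockout dosed from 2 hpf, diquat raised SEL1L3 (1.71 ± 0.38), dock8 (1.15 ± 0.22), the intestinal protease gene mep1a.2 (1.27 ± 0.29), agxtb (1.12 ± 0.24) and hmox1a (185 ± 35.9 to 335 ± 109.8, adjusted p = 0.0384). It lowered the nucleolar gene nolc1 (-0.88 ± 0.20), the chromatin remodeller gene chd8 (-0.87 ± 0.22) and the neural crest gene pax3a (-1.47 ± 0.39). Of 13 mitochondrial transcripts 2 rose, mt-nd4l (0.92) and mt-nd5 (0.81), and 7 adjusted over the list alone (camera adjusted p = 0.000293; adjusted p = 0.559 with an estimated correlation). The total of 242 rises and 49 falls became 441 and 1 without diquat replicate 2 and 3 in turn. It was 0, 0 and 689 without water replicate 1, 2 and 3 in turn. With TMM rescaling 70 genes passed, without the low-value filter 8, and limma called 0 when only these 6 libraries were fitted. None of the named genes kept its call in each fit with 1 library left out. For tBOOH in the knockout limma called 0 genes, with 477 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0 each. The knockout tBOOH count was 1 without tBOOH replicate 3. It was 1 and 7 without water replicate 1 and 2 in turn. Genes whose change with diquat differed between the genotypes numbered 73 (61 with a more positive change in the knockout). Of those named next, dnajb9b, cacna1ha and mchr1b are among the 7 genes given above that also differed between the strains. The calls included dock8 (difference 2.39 ± 0.30), dnajb9b (2.44 ± 0.39), cacna1ha (ENSDARG00000097913, a T-type calcium channel gene, 2.302 ± 0.36), nebl (2.32 ± 0.40) and, in the other direction, mchr1b (-1.26 ± 0.25) and emilin3a (-1.69 ± 0.39). The number of such genes was 40 without wildtype diquat replicate 2. It was 35 without wildtype water replicate 3. It was 35 without knockout diquat replicate 3. It was 48, 43 and 151 without knockout water replicate 1, 2 and 3 in turn. The call of emilin3a ended without wildtype diquat replicate 1 or 2, wildtype water replicate 1 or 3, knockout diquat replicate 1 or 3 or knockout water replicate 1 or 2 (adjusted p up to 0.0993). For tBOOH 1 gene differed between genotypes, si:ch73-345h12.2 (log2 2.49, adjusted p = 0.0356, chosen after its values were seen), and 9 of 100 labellings gave as many. More genes differed with a pseudocount of 5, the replicate block, edgeR, DESeq2 and library quality weights, as given below. With only the compared groups in the fit 0 did. The number for tBOOH was 218, 0 and 0 without wildtype tBOOH replicate 1, 2 and 3 in turn. It was 0 without wildtype water replicate 1 or 2. It was 0 without knockout tBOOH replicate 1, 2 or 3. It was 0, 413 and 0 without knockout water replicate 1, 2 and 3 in turn.

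Knockout and wildtype pools in water already differed widely in the 2 hpf series. CFAP70, a ciliary gene, reached 249 ± 84.7 in the knockout with no read in wildtype, at least 307-fold higher by the floor of 3 reads over the group. The orphan receptor gene gpr19 was at least 79.0-fold higher (64.0 ± 5.34), and dgkb, at 183 ± 54.8 in wildtype, was at least 220.5-fold lower. The cochaperone gene dnajb9b (638 ± 163 against 11.4 ± 2.47), the muscle myosin-binding gene mybpc1 (5.65 ± 0.36) and the helicase gene dhx40 (4.69 ± 0.33) were higher, and LECT2 (1 to many, ENSDARG00000086483, -4.80 ± 0.66) and the lipid kinase gene pik3c2b (-3.78 ± 0.39) lower. Ribosomal protein genes were higher for 63 of 76 (67 adjusted over the list alone; median 0.70, adjusted p = 2.77e-23, adjusted p = 0.141 with an estimated correlation). Of 40 cell cycle genes 16 were lower and 2 higher (18 and 2 adjusted over the list alone; adjusted p = 0.00627, adjusted p = 0.283 with an estimated correlation), among them mcm2 (-1.15) and cdc20 (-1.35). Of 30 unfolded protein genes 10 were higher and 0 lower by limma, also adjusted over the list alone, including the chaperone gene calr (1.72) and asns (1.63), with adjusted p = 0.0263 and adjusted p = 0.141 with an estimated correlation. The mitochondrial gene mt-nd6 was higher as well (11425 ± 3935 against 3429 ± 205). In all, 1238 genes were higher and 1198 lower in the knockout, and between 1656 and 2624 passed without any 1 library. The call of unfolded protein and integrated stress response ended without wildtype water replicate 3 (adjusted p up to 0.0568).

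At 48 hpf tBOOH raised genes of redox defence in both genotypes, and diquat moved few genes in the main fit. In wildtype, tBOOH raised the thioredoxin gene txn from 11.5 ± 3.02 to 85.3 ± 9.79 (log2 change 2.81 ± 0.29, adjusted p = 6.21e-05), the glutathione transferase gene gstp1 from 38.8 ± 12.5 to 179 ± 20.1 (log2 change 2.22 ± 0.39, adjusted p = 0.016), the peroxiredoxin gene prdx1 (2.09 ± 0.32) and zgc:109934 of the iron and heme list, named fthl31 in the reference (2.89 ± 0.39). The collagen gene col4a3 (1.32 ± 0.25), cacna1ha (1.14 ± 0.21) and the glycolytic gapdhs (0.88 ± 0.16) also rose. Of these cacna1ha also differed between the strains, and a pool difference stays open for it. Its log2 change with diquat against the same water libraries was 1.13. In the knockout txn (2.95 ± 0.29, from 14.02 ± 5.58 to 114 ± 36.9), prdx1 (2.66 ± 0.32), gstp1 (2.43 ± 0.39), zgc:109934 (3.53 ± 0.39), the prostaglandin reductase gene PTGR1 (1 to many, 5.02 ± 0.56), the glutathione transferase gene gsto2 (2.64 ± 0.48) and the transketolase gene tktb (1.56 ± 0.30) rose. Of 17 Nrf2-type genes 3 rose in wildtype (6 adjusted over the list alone; camera adjusted p = 1.77e-06, adjusted p = 0.165 with an estimated correlation) and 4 in the knockout (9 over the list alone; adjusted p = 5.95e-10 and adjusted p = 0.0775 with an estimated correlation). Both genotypes shared 6 calls, where independence gives 0.021 rises and 0.000823 falls: txn, gstp1, prdx1, PTGR1, zgc:109934 and CABZ01059415.2. Without knockout tBOOH replicate 1 they shared 13, with only the compared groups in the fit 3 and with library quality weights 24. Against diquat, txn (2.90 ± 0.29), prdx1 (2.12 ± 0.32) and PTGR1 (3.204, chosen after its values were seen) were higher in tBOOH, the 3 genes called. Their number was 1 without diquat replicate 3. It was 1 without tBOOH replicate 1, 2 or 3. The call of prdx1 ended without diquat replicate 3 or tBOOH replicate 1, 2 or 3 (adjusted p up to 0.116). In total tBOOH raised 12 and lowered 4 wildtype genes. The wildtype total was 8, 6 and 8 without tBOOH replicate 1, 2 and 3 in turn. It was 9 and 8 without water replicate 2 and 3 in turn. In the knockout 17 rose and 2 fell, and this total was 270 and 12 without tBOOH replicate 1 and 3 in turn. It was 33 without water replicate 2. Several wildtype calls depended on single libraries. The call of gstp1 ended without tBOOH replicate 1, 2 or 3 or water replicate 1 or 2 (adjusted p up to 0.114). The call of col4a3 ended without tBOOH replicate 1, 2 or 3 or water replicate 1, 2 or 3 (adjusted p up to 0.18). The call of cacna1ha ended without tBOOH replicate 1, 2 or 3 or water replicate 1 or 3 (adjusted p up to 0.22). The call of gapdhs ended without tBOOH replicate 2 or 3 or water replicate 1, 2 or 3 (adjusted p up to 0.151). Among the knockout calls 2 did so too. The calls of gsto2 and tktb ended without tBOOH replicate 2 or 3 or water replicate 1 or 3 (adjusted p up to 0.201 and 0.295).

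Diquat from 48 hpf raised 1 wildtype gene, mchr1b (112 ± 25.5 to 262 ± 68.1, log2 change 1.21 ± 0.22, adjusted p = 0.0483), and lowered tmc8, zgc:113363 and CU302316.1 (log2 -3.33, -1.36 and -1.32, chosen after their values were seen). As mchr1b also differed between the strains, a pool difference stays open for it. Its log2 change with tBOOH against the same water libraries was 0.92. With the replicate number as a block limma called 0 genes (521 genes at an unadjusted p under 0.05 without the block). The count of 4 was 0, 1 and 0 without diquat replicate 1, 2 and 3 in turn. It was 1 and 0 without water replicate 1 and 3 in turn. The call of mchr1b ended without diquat replicate 1 or 3 or water replicate 1 or 3 (adjusted p up to 0.404). In the knockout limma called 0 genes after diquat, with 319 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 1, without water replicate 2 limma called 1, and with library quality weights it called 286. The interaction test called 0 genes for either oxidant by limma, edgeR and DESeq2 alike, with 388 genes for diquat and 622 for tBOOH at an unadjusted p under 0.05. With library quality weights it called 2 genes for diquat and 400 for tBOOH. As sets, 8 lists were called by camera for diquat and 8 for tBOOH, among them neurons (median differences -0.25 and -0.40) and liver (-0.75 and 1.03). None of these calls held with an estimated correlation (lowest adjusted p 0.213 for diquat and 0.384 for tBOOH) or with fry (lowest 0.339 and 0.29). In the fits with 1 library left out, 0 of the diquat lists and 1 of the tBOOH lists, neurons, kept the camera call each time. The knockout libraries also split within their groups at this stage (next paragraph), and apoa1b of the liver list followed that split, with 19.5, 364 and 28.8 in knockout water and 22.7, 808 and 423 in knockout tBOOH. A difference between genotypes in response is therefore left open at this stage. On simulated data the same interaction test recovered 60% of 4-fold and 9% of 2-fold differences.

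In 48 hpf water the knockout had lower levels of several red-cell transcripts than wildtype, and muscle genes were called lower as a set by camera alone. Of 27 erythroid genes 5 were lower (10 adjusted over the list alone; median -0.79, camera adjusted p = 5.9e-05, and 0.0362 as the adjusted p with an estimated correlation). They included the embryonic globins hbae3 (23.2 ± 16.53 against 105 ± 32.8) and hbbe2 (-3.10 ± 0.49), and alas2, the first enzyme of heme synthesis in red cells (4.26 ± 1.29 against 23.6 ± 1.83, log2 change -2.25 ± 0.40, adjusted p = 0.00338). The embryonic globin hbbe1.1, too low to be tested and chosen after its values were seen, went the other way, with 3.895, 13.01 and 3.2 in the 3 knockout water libraries and no read in wildtype water. Of 37 skeletal muscle genes 2 were lower (8 adjusted over the list alone), myhz2 (-1.45 ± 0.34) and tnnt3a (-1.12 ± 0.24), with camera adjusted p = 5.14e-09 and adjusted p = 0.49 with an estimated correlation (0.157 with fry). Neuronal genes leaned the other way, 3 of 34 being higher (11 adjusted over the list alone), such as the synaptic snap25a (0.88 ± 0.21), with adjusted p = 9.6e-09 and adjusted p = 0.49 with an estimated correlation. CFAP70 (7.41 ± 0.43), dnajb9b (5.66 ± 0.26), ikbkap (3.28 ± 0.24) and dhx40 (3.17 ± 0.31) were higher, and the sarcoglycan gene sgcg (-3.66 ± 0.58), wdpcp (-4.19 ± 0.72) and the enolase gene eno3 (-1.88 ± 0.26) lower. Across these groups the knockout libraries themselves split: water replicates 1 and 3, diquat 2 and tBOOH 1 held more of the nuclear RNA malat1 (3956, 2884, 3270 and 3536, against 1111 to 2320 in the other knockout libraries) and of mt-nd6 (16710, 13960, 13760 and 14850), and less apolipoprotein apoa1b (19.5, 28.8, 31.0 and 22.7, against 81.2 to 808). In wildtype water malat1 was 1072, 994.6 and 1440, below each knockout water library (lowest 1776). In diquat the genotypes lay apart too (highest wildtype 1213, lowest knockout 1827). In tBOOH they did not: knockout replicates 2 and 3 held 1111 and 1466, against 1308 to 1493 in wildtype. Erythroid hbae3 was 14.6 and 12.8 in knockout water 1 and 3 and 42.3 in water 2, and at least 81.2 in each wildtype water library. In total 147 genes were higher and 95 lower, and 111 genes passed without the libraries under 0.65 M reads. With library quality weights far more passed, as given below. The total in the main fit became 155, 111 and 122 without wildtype water replicate 1, 2 and 3 in turn. It was 73, 808 and 77 without knockout water replicate 1, 2 and 3 in turn. The call of hbae3 ended without wildtype water replicate 2 or knockout water replicate 1 or 3 (adjusted p up to 0.111). The call of myhz2 ended without wildtype water replicate 1, 2 or 3 or knockout water replicate 1 or 3 (adjusted p up to 0.175). The calls of tnnt3a and snap25a ended without wildtype water replicate 2 or 3 or knockout water replicate 1 or 3 (adjusted p up to 0.13 and 0.13).

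At 96 hpf diquat lowered digestive enzymes and raised redox genes in wildtype embryos. The pancreatic amylase gene amy2a fell from 81.01 ± 18.6 to 21.2 ± 5.94 (log2 change -1.90 ± 0.37, adjusted p = 0.0151), and the trypsin genes prss59.1 (-1.47 ± 0.28) and prss59.2 (-1.41 ± 0.24), the elastase gene ela2 (-1.40 ± 0.30), alas2 (-1.37 ± 0.28) and the keratin gene krt17 (-1.02 ± 0.22) fell. PTGR1 rose from 19.9 ± 7.76 to 135 ± 9.49 (log2 change 2.78 ± 0.38, adjusted p = 0.000656), with gstp1 (1.11 ± 0.17), txn (1.16 ± 0.24) and the otolith gene stm (1.22 ± 0.18). Of 16 exocrine pancreas genes 5 fell (15 adjusted over the list alone), with a median of -1.47, camera adjusted p = 5.19e-34 and adjusted p = 0.00202 with an estimated correlation. The 21 intestine genes were lower as a set (median -0.65, adjusted p = 2.02e-09, adjusted p = 0.00541 with an estimated correlation) although limma called 0 of them (6 fell adjusted over the list alone). Of 20 Nrf2-type genes 2 rose (4 over the list alone; adjusted p = 2.8e-06, adjusted p = 0.00202 with an estimated correlation). In total 13 genes rose and 15 fell. The total was 7 and 4 without diquat replicate 1 and 2 in turn. It was 5, 9 and 13 without water replicate 1, 2 and 3 in turn. The call of amy2a ended without diquat replicate 1 or 2 or water replicate 1 or 2 (adjusted p up to 0.259). The call of prss59.1 ended without diquat replicate 1 or 2 or water replicate 1 or 3 (adjusted p up to 0.142). The call of prss59.2 ended without diquat replicate 2 or water replicate 1 (adjusted p up to 0.119). The calls of ela2, alas2, krt17 and txn ended without diquat replicate 1 or 2 or water replicate 1, 2 or 3 (adjusted p up to 0.48, 0.299, 0.325 and 0.373).

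The 96 hpf wildtype embryos answered tBOOH with redox, heat shock and glycolysis genes. PTGR1 rose from 19.9 ± 7.76 to 311 ± 40.0 (log2 change 3.97 ± 0.38, adjusted p = 7.85e-08), txn from 50.8 ± 5.01 to 359 ± 42.5, the inducible chaperone gene hsp70l from 5.84 ± 4.74 to 65.4 ± 23.1 and gstp2 from 5.33 ± 2.87 to 51.0 ± 0.817. Of 20 Nrf2-type genes 9 rose (10 adjusted over the list alone; median 0.78, adjusted p = 2.48e-05 with an estimated correlation), and of 37 heat shock genes 11 (18 over the list alone; median 0.81, adjusted p = 0.00393 likewise). Of 37 hypoxia and glycolysis genes 7 rose (7 over the list alone; adjusted p = 0.00451 with an estimated correlation), among them the glycolysis regulator gene pfkfb3 (2.14 ± 0.26) and the pyruvate dehydrogenase kinase gene pdk2b (1.98 ± 0.24). The stress transcription factor genes atf3 (2.02 ± 0.36) and fosab (ENSDARG00000097234, 1.62 ± 0.28) rose, as did 5S_rRNA (ENSDARG00000104133, 4.93 ± 0.58), a transcript without a poly(A) tail. Of 31 cell cycle genes 6 fell (10 adjusted over the list alone; adjusted p = 0.000811 with an estimated correlation), including the proliferation marker gene mki67 (99.1 ± 4.37 to 45.3 ± 7.34) and top2a (-1.07 ± 0.22), beside krt17 (-1.91 ± 0.22) and krt5 (-1.01 ± 0.16). Exocrine pancreas genes were lower as a set (median -0.70; camera adjusted p = 1.74e-07, adjusted p = 0.0889 with an estimated correlation), with 1 of 16 called and 2 over the list alone, and so were intestine genes (median -0.33; adjusted p = 0.019 and 0.167 likewise), with 0 of 21 called by limma and 0 over the list alone. The glutathione list had a median of -0.09, a mean of 0.33 and an upward camera call (adjusted p = 0.0238; adjusted p = 0.141 with an estimated correlation), so its median and its test differ in sign; 4 of 19 members rose (4 rose and 2 fell adjusted over the list alone). In total 175 genes rose and 88 fell. The sum was 121 and 135 without tBOOH replicate 1 and 3 in turn. It was 139, 139 and 160 without water replicate 1, 2 and 3 in turn. Set directly against diquat, tBOOH left hsp70l (3.39 ± 0.42), pdk2b (2.94 ± 0.24), txn (1.63 ± 0.24) and pfkfb3 (2.03 ± 0.26) higher and krt5 (-1.12 ± 0.16) and s100t (-1.35 ± 0.22) lower, among 134 higher and 58 lower genes. Heat shock (10 of 37 higher, 15 higher and 1 lower over the list alone) and Nrf2-type genes (3 of 20, 7 over the list alone) were higher and cell cycle genes lower (2 of 31, 3 over the list alone) in tBOOH than in diquat, with adjusted p = 0.00986, 0.00115 and 0.00207 with an estimated correlation. This count was 75, 104 and 86 without diquat replicate 1, 2 and 3 in turn. It was 70, 123 and 73 without tBOOH replicate 1, 2 and 3 in turn. The call of glutathione enzymes ended without tBOOH replicate 1 or 3 (adjusted p up to 0.0617). The call of intestine ended without tBOOH replicate 1 or water replicate 1 (adjusted p up to 0.0944). Each other gene and list named for these contrasts kept its call in every fit with 1 library left out.

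**Figure D1:**
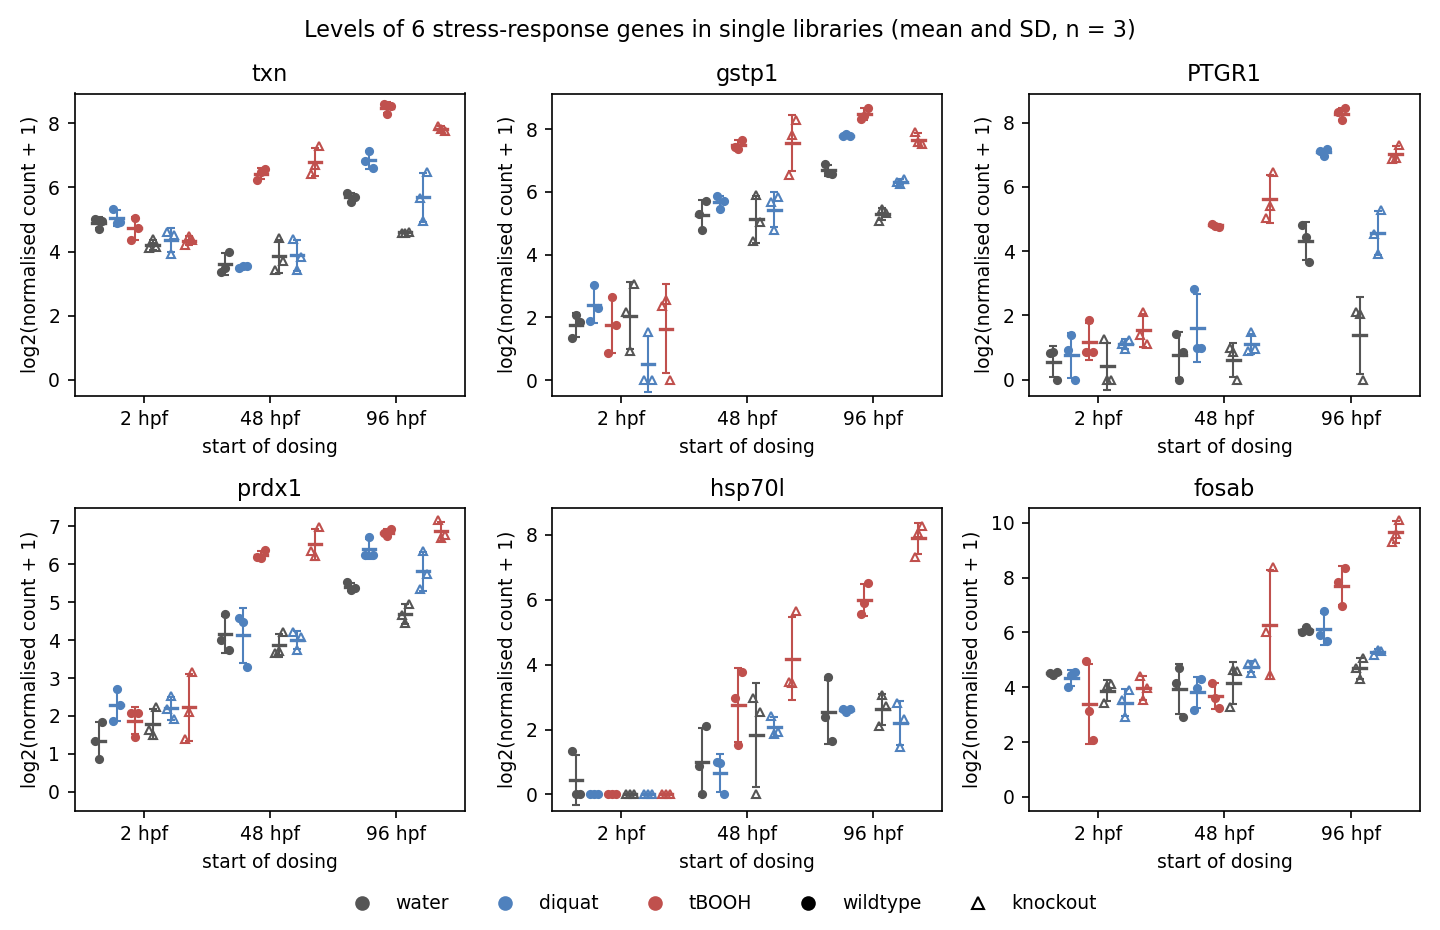
Level of 6 genes in each library as log2(normalised count + 1), by start of dosing, with wildtype as filled circles, knockout as open triangles, bars for the mean and whiskers for the SD of 3 libraries. In wildtype at 96 hpf txn rose from 50.8 in water to 116 in diquat and 359 in tBOOH, and hsp70l rose in tBOOH to 65.4 in wildtype and 245 in the knockout.

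Knockout embryos dosed with diquat from 96 hpf raised the organic anion exporter gene abcc2 (2.24 ± 0.33), zgc:109934 (2.12 ± 0.26), gsto2 (13.4 ± 4.08 to 41.3 ± 4.02), gstp1 (38.3 ± 4.99 to 79.3 ± 4.16), prdx1 (1.12 ± 0.23), stm (1.11 ± 0.18) and the complement gene c3a.1 (1.63 ± 0.31). Of 20 Nrf2-type genes 4 rose (5 adjusted over the list alone), of 19 glutathione genes 3 (3 over the list alone) and of 16 iron and heme genes 1 (2 over the list alone), with adjusted p = 0.00102, 0.0167 and 0.0167 with an estimated correlation. Cell-type lists moved as well, 14 lists being called by camera in all: liver (median 0.38; 1 of 43 called, 8 over the list alone) and epidermis (0.41; 1 of 40, 4 over the list alone) were higher, and photoreceptors (-0.21) and neurons (-0.15) lower with 0 called. With an estimated correlation the adjusted p of these 4 lists was 0.166, 0.127, 0.293 and 0.302. In total 36 genes rose and 0 fell by limma (1104 at an unadjusted p under 0.05 in either direction), and 8 rises were shared with wildtype, where independence gives 0.0409, among them PTGR1, gstp1, txn and stm. The shared calls were 4 and 3 without wildtype diquat replicate 1 and 2, 4, 4 and 5 without wildtype water replicate 1, 2 and 3, 5 without knockout water replicate 3, 5 without the low-value filter and 2 with only the compared groups in the fit. Without the libraries under 0.65 M reads 65 genes passed, and 2 when only these 6 libraries were fitted. The total was 114 and 177 without diquat replicate 1 and 3 in turn. It was 21 without water replicate 3. The call of prdx1 ended without diquat replicate 2 or water replicate 1 or 2 (adjusted p up to 0.0946). The call of c3a.1 ended without water replicate 3 (adjusted p up to 0.121).

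With tBOOH the 96 hpf knockout gave the largest set of calls of the oxidant contrasts in the main fit, 624 rises and 233 falls. With library quality weights it gave 1191 calls, and tBOOH in the 48 hpf knockout gave more, 1742. The immediate early gene fosab rose from 25.5 ± 6.78 to 836 ± 248, hsp70l from 5.39 ± 2.01 to 245 ± 76.0, gsto2 from 13.4 ± 4.08 to 240.2 ± 81.6 and the sarcomere gene tcap from 13.4 ± 3.01 to 322 ± 60.7. PTGR1 (5.64 ± 0.38), the muscle ubiquitin ligase gene fbxo32 (4.82 ± 0.67), atf3 (3.88 ± 0.36), the cochaperone gene bag3 (3.90 ± 0.39), alas2 (2.096 ± 0.28), amy2a (2.61 ± 0.37) and ela2 (2.13 ± 0.30) rose, and krt17 (-2.34 ± 0.22), mki67 (-1.28 ± 0.21) and the neuronal tubulin gene tubb5 (-1.16 ± 0.17) fell. Heat shock genes rose for 19 of 37 and fell for 1 (24 and 2 adjusted over the list alone), immediate early genes rose for 16 of 30 (19 over the list alone), Nrf2-type for 12 of 20 (13), inflammation for 9 of 20 (11), iron and heme for 8 of 16 (8), hypoxia and glycolysis for 10 of 37 (13) and glutathione genes for 5 of 19 with 1 fall (6 and 1). The p53 targets rose for 5 of 21 (8 over the list alone), unfolded protein genes for 6 of 41 (7), liver genes for 15 of 43 with 1 fall (23 and 1), exocrine pancreas for 8 of 16 (11), intestine for 3 of 21 (6) and glia for 3 of 16 with 1 fall (5 and 1), while 9 of 31 cell cycle genes fell (13). With an estimated correlation the adjusted p of these 14 lists was, in that order, 0.00181, 0.00195, 4.18e-05, 0.00232, 0.00402, 0.00919, 0.00919, 0.00919, 0.0387, 0.0423, 0.0377, 0.0387, 0.033 and 0.00205. Without any 1 library the total stayed between 572 and 720. Wildtype and knockout shared 156 rises and 54 falls, where independence gives 9.55 and 1.79, with 1 gene moving in opposite directions. These 210 were 103 and 106 without wildtype tBOOH replicate 1 and 3, and 122, 120 and 136 without wildtype water replicate 1, 2 and 3. With only the compared groups in the fit they were 353, with library quality weights 363, and 331 without the libraries under 0.65 M reads. The call of unfolded protein and integrated stress response ended without tBOOH replicate 1 (adjusted p up to 0.0558). It also ended without the libraries under 0.65 M reads.

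The response to tBOOH differed between genotypes at 96 hpf for 37 genes, each with a more positive change in the knockout. Of 100 labellings, the real one and others redrawn within each genotype, 11 gave as many genes (highest 362), so chance was not excluded for this count. Such redrawing can also turn a response shared by the genotypes into a difference, so it decides little. They were led by fosab (difference 3.36 ± 0.40, adjusted p = 3.5e-05), the pancreatic amy2a (3.28 ± 0.53), cpa5 (3.15 ± 0.62), ela2 (2.90 ± 0.43) and prss59.2 (2.12 ± 0.34), alas2 (2.74 ± 0.39), zgc:109934 (2.44 ± 0.36) and gsto2 (1.94 ± 0.30). Of 16 exocrine pancreas genes 8 differed (14 adjusted over the list alone; median difference 1.83, adjusted p = 0.00836 with an estimated correlation). This list had a median of -0.70 in wildtype tBOOH against water and 1.07 in the knockout. Immediate early genes differed for 1 of 30 (4 over the list alone; median 0.83), glutathione genes for 2 of 19 (2; 0.59) and iron and heme genes for 1 of 16 (2; 0.50), with adjusted p = 0.0108, 0.0249 and 0.0268 with an estimated correlation. Intestine (7 of 21 over the list alone), heat shock (6 up and 1 down of 37), inflammation (2 of 20), liver (11 of 43) and Nrf2-type lists (2 of 20) differed as sets without a single call by limma, with adjusted p = 0.00853, 0.043, 0.0268, 0.0435 and 0.043 with an estimated correlation. Several of these genes started lower in knockout water: amy2a was 2.56 there and 81.01 in wildtype water, and gsto2 13.4 and 119. The count was 24 without wildtype tBOOH replicate 1. It was 23 without wildtype water replicate 1. For diquat 1 gene differed, ihha (ENSDARG00000097968, a hedgehog ligand gene, log2 3.23, adjusted p = 0.0130, chosen after its values were seen), and 10 of 100 labellings gave as many. The number for diquat was 0 without wildtype diquat replicate 1, 2 or 3. It was 0, 0 and 2 without wildtype water replicate 1, 2 and 3 in turn. It was 9, 2 and 74 without knockout diquat replicate 1, 2 and 3 in turn. It was 2, 0 and 4 without knockout water replicate 1, 2 and 3 in turn. The liver, pancreas and intestine lists had positive median differences for diquat (0.82, 1.203 and 0.89), whose adjusted p with an estimated correlation was 0.0637, 0.0591 and 0.057. The call of cpa5 ended without wildtype tBOOH replicate 1, wildtype water replicate 1, knockout tBOOH replicate 1 or knockout water replicate 3 (adjusted p up to 0.0728). The call of Nrf2-type antioxidant genes ended without wildtype tBOOH replicate 2 or knockout tBOOH replicate 1 (adjusted p up to 0.0889). It also ended with a pseudocount of 5, without the low-value filter and without the libraries under 0.65 M reads, and the call of iron and heme genes ended without the low-value filter.

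In 96 hpf water the knockout held far less liver, pancreas and gut mRNA than wildtype. Of 43 liver genes 39 were lower (40 lower and 2 higher adjusted over the list alone; median -2.37), of 16 exocrine pancreas genes 15 (16 over the list alone; -2.35) and of 21 intestine genes 16, with 1 higher (16 and 1; -2.30). The lipoprotein gene apobb.1 was 30.1 ± 10.2 against 652 ± 97.2 (log2 change -4.44 ± 0.24, adjusted p = 2e-13), and the transferrin gene tfa (-4.08 ± 0.30), apom (-4.09 ± 0.40), amy2a (-4.58 ± 0.37), the carboxypeptidase gene cpa5 (-5.06 ± 0.44) and the intestinal vil1 (-3.32 ± 0.29) were lower. Redox genes were lower too, 16 of 20 Nrf2-type genes with 1 higher (16 and 1 over the list alone) and 13 of 19 glutathione genes (16 over the list alone), among them gstp1 (38.3 ± 4.99 against 103 ± 13.8), gsto2 (-3.09 ± 0.22), abcc2 (-3.53 ± 0.33) and nqo1 (-1.99 ± 0.32). Iron and heme genes were lower for 9 of 16 (9), heart genes for 5 of 9 (5) and aryl hydrocarbon receptor targets for 3 of 7 (3), and neuronal genes were higher for 23 of 40 with 1 lower (26 and 1) and mitochondrial transcripts for 4 of 13 (5). With an estimated correlation the adjusted p of these 10 lists was 0.00249, 0.0124, 0.000776, 0.000776, 0.00249, 0.00849, 0.0373, 0.0456, 0.0235 and 0.0456, in that order. Epidermis (23 of 40 lower, 25 lower and 1 higher over the list alone), photoreceptor (20 of 40 higher and 1 lower, 24 and 1) and ribosomal protein genes (29 of 76 higher, 43) had adjusted p = 0.0713, 0.0737 and 0.081 with an estimated correlation. CFAP70 (7.11 ± 0.31), dnajb9b (5.20 ± 0.46), dhx40 (4.13 ± 0.40) and ikbkap (3.51 ± 0.31) were higher, and mt-nd6 was higher as well (19307 ± 1473 against 10998 ± 1289). In total 1134 genes were higher and 1501 lower, between 1839 and 2206 without any 1 library. The call of mt-nd6 ended without wildtype water replicate 1 or 2 or knockout water replicate 1, 2 or 3 (adjusted p up to 0.124).

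**Figure D2:**
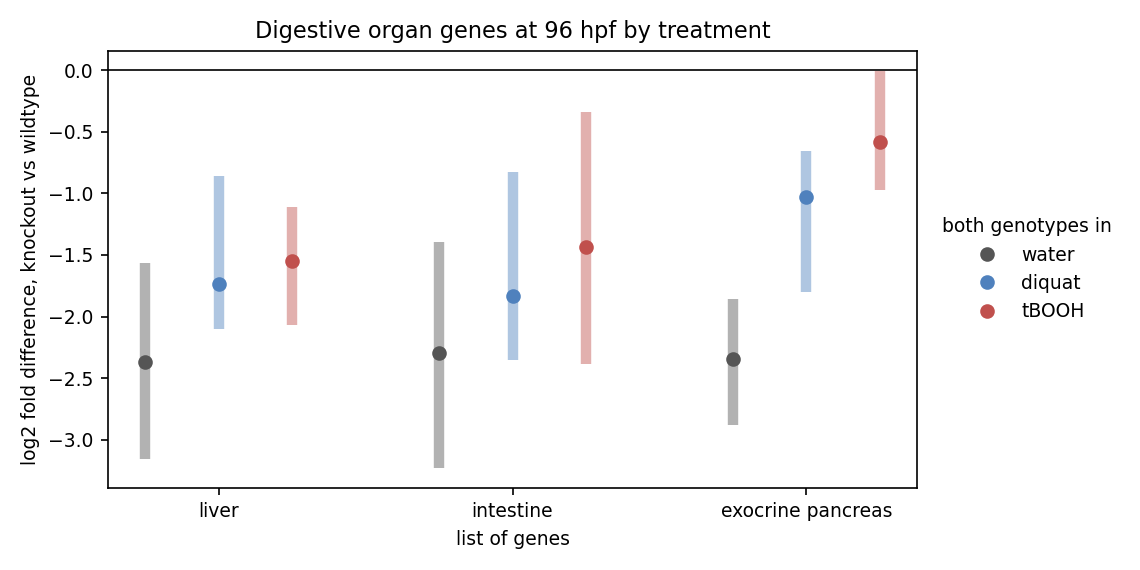
Median log2 difference between knockout and wildtype (points) with quartiles over genes (bars) for the liver, intestine and exocrine pancreas lists at 96 hpf, with both genotypes in water, diquat or tBOOH. The liver median lay at -2.37 in water, -1.74 in diquat and -1.55 in tBOOH, and the pancreas median at -2.35, -1.03 and -0.58.

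The wildtype responses to each oxidant differed between stages for 44 genes with diquat and 116 with tBOOH, by an F test in limma over all libraries. For tBOOH the thioredoxin gene txn did not rise in the 2 hpf series (log2 -0.18, 2.81 and 2.79 from 2 hpf to 96 hpf, adjusted p = 2.59e-07), and PTGR1 (0.63, 4.03 and 3.97; adjusted p = 0.00361) and hsp70.1 (-0.45, 1.64 and 3.33; adjusted p = 0.00247) followed a like order. The adhesion receptor gene adgre10 (0.11, -0.51 and 2.14; adjusted p = 7.59e-07), krt17 (0.31, -0.37 and -1.91; adjusted p = 6.01e-05) and gstp2 (0.00, 1.31 and 3.13; adjusted p = 0.000727) moved most at 96 hpf. At 2 hpf hsp70.1 had a change of -0.4468 with diquat and with tBOOH alike, and gstp2 a change of 0 with both. Such equal values mark genes at or near the floor, so a lack of response was not measured for them there. For diquat the calcium channel gene cacna1ha (-1.71, 1.13 and 0.00; adjusted p = 9.28e-07), stm (-0.41, 0.35 and 1.22; adjusted p = 0.000496) and alas2 (0.62, 1.14 and -1.37; adjusted p = 0.0417) differed. Of these cacna1ha is among the 7 genes that also differed between the strains, for which a pool difference stays open. Its changes with tBOOH, against the same water libraries, were -1.01, 1.14 and 0.05. The diquat count stayed between 31 and 43 without any 1 library. The tBOOH count was 211, 68 and 50 without 2 hpf tBOOH replicate 1, 2 and 3 in turn. It was 64 and 72 without 2 hpf water replicate 1 and 2 in turn. It was 77 without 48 hpf tBOOH replicate 1. It was 54 and 52 without 96 hpf tBOOH replicate 1 and 3 in turn. It was 70, 66 and 62 without 96 hpf water replicate 1, 2 and 3 in turn.

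Wildtype calls for the 2 oxidants overlapped at each stage. At 2 hpf 8 genes were shared in direction (6 up, 2 down, with 1 more in opposite directions), where independence gives 0.41 and 0.64, among them slc7a8a, appb, cacna1ha, crabp2a and hoxb8b. At 48 hpf both oxidants lowered CU302316.1 and zgc:113363, where independence gives 0.00123. At 96 hpf 8 were shared (7 up, 1 down, 1 opposite; independence gives 0.199 and 0.115), among them PTGR1, gstp1, txn and 5S_rRNA up and krt17 down. The 2 contrasts of a stage use the same 3 water libraries, so part of the excess may come from shared controls. In 20 simulations with shared controls and no response there were 0 shared calls, which decides little, since unchanged groups give hardly any calls to share. The correlation of the 2 responses over all tested genes was 0.271, 0.615 and 0.44 from 2 hpf to 96 hpf, against 0.502, 0.499 and 0.502 in these simulations. Their covariance was 0.0533, 0.0931 and 0.0809, against 0.0538, 0.0643 and 0.0664. The 2 hpf overlap was 4 without diquat replicate 3. It was 1 and 0 without tBOOH replicate 2 and 3 in turn. It was 0 without water replicate 1 or 2. The 48 hpf overlap was 0 without diquat replicate 1, 2 or 3. It was 0 without tBOOH replicate 1, 2 or 3. It was 1 and 0 without water replicate 1 and 3 in turn. The 96 hpf overlap was 4 and 3 without diquat replicate 1 and 2 in turn. It was 4, 5 and 5 without water replicate 1, 2 and 3 in turn.

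**Figure D3:**
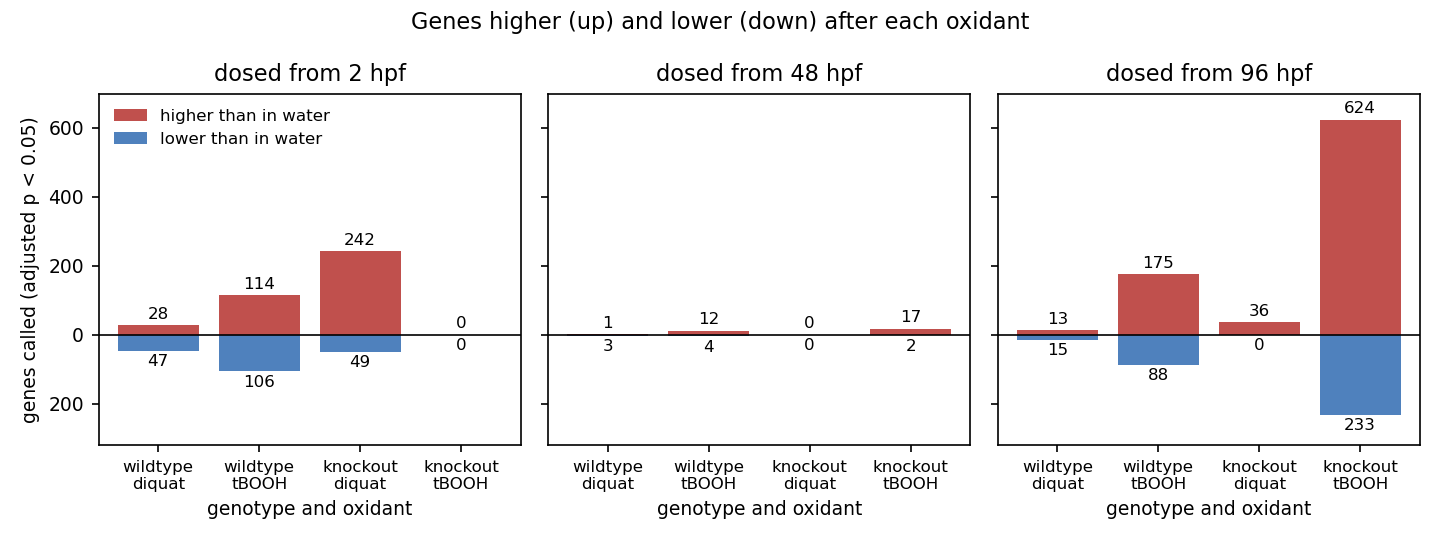
Number of genes called higher (up) and lower (down) than in water at an adjusted p under 0.05, for each genotype and oxidant, by start of dosing. The counts run from 0 in the 2 hpf knockout after tBOOH and the 48 hpf knockout after diquat to 624 up and 233 down in the 96 hpf knockout after tBOOH.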

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

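The tests of parental genotypes, of slower development, of a state of the water libraries and of counting on the opposite strand were chosen after the result they bear on was seen.

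Responses that differed between genotypes or stages by a test of the difference itself are listed here. For diquat at 2 hpf 73 genes differed between genotypes. Log2 differences were 2.44 for dnajb9b, 2.39 for dock8, 2.32 for nebl, 2.302 for cacna1ha, 2.22 for tnnt2c, 2.19 for cryabb and 1.27 for ca9. Negative ones were -1.04 for ccng1, -1.15 for fcf1, -1.26 for mchr1b, -1.29 for col18a1, -1.69 for emilin3a and -1.90 for cyp26c1. As many genes came from 3 of 100 labellings, the real one included (highest other 80). Redrawing within each genotype breaks the responses themselves and can turn a shared response into a difference. For each genotype difference here, such labellings therefore cannot decide whether the difference itself is chance. For tBOOH at 2 hpf 1 gene differed, and 9 of 100 labellings gave as many (highest 1013), so chance was not excluded. At 48 hpf limma called 0 for diquat and 0 for tBOOH (388 and 622 genes at an unadjusted p under 0.05), and edgeR and DESeq2 called 0 each. Any labelling reaches a count of 0, so the share of 100 of 100 decides nothing (highest 79 and 1184). For diquat at 96 hpf 1 gene differed, and 10 of 100 labellings gave as many (highest 12), so chance was not excluded.

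For tBOOH at 96 hpf 37 genes differed between genotypes, with log2 differences of 3.36 for fosab, 3.28 for amy2a, 3.15 for cpa5, 2.90 for ela2, 2.74 for alas2, 2.47 for ela2l, 2.44 for zgc:109934, 2.12 for prss59.2, 1.94 for gsto2 and 1.48 for zgc:158387. List medians differed by 0.31 for Nrf2-type antioxidant genes, 0.59 for glutathione enzymes, 0.72 for heat shock proteins, 0.83 for immediate early genes, 0.61 for inflammation, 0.50 for iron and heme handling, 0.71 for liver, 1.83 for exocrine pancreas and 0.81 for intestine. Of 100 labellings, the real one and others redrawn within each genotype, 11 gave as many genes (highest 362), so chance was not excluded for this count. Without single libraries the count was 24 (wildtype tBOOH replicate 1) or 23 (wildtype water replicate 1).

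Between stages 44 wildtype diquat responses differed, with adjusted p in limma of 9.28e-07 for cacna1ha, 0.000496 for stm, 0.0147 for ttc14, 0.0245 for dock8 and 0.0417 for alas2. Both cacna1ha and ttc14 are among the 7 genes listed below that also differed between the strains. The tBOOH responses of 116 genes differed, with 2.59e-07 for txn, 7.59e-07 for adgre10, 6.01e-05 for krt17, 0.000558 for cacna1ha, 0.000727 for gstp2, 0.00247 for hsp70.1, 0.00357 for 5S_rRNA, 0.00361 for PTGR1, 0.0052 for slc7a8a and 0.00703 for glula. In the 2 hpf series gstp2 and hsp70.1 lay at or near the floor. As many genes came from 1 of 100 labellings, the real one, for diquat (highest other 29) and 3 of 100 for tBOOH (highest 178). Redrawing within each stage breaks the responses themselves, so these shares do not test a difference between stages alone.

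For each of the other gene counts the 6 libraries make 10 splits, which are too few for a share under 0.05. Real and highest other counts at 2 hpf were 75 and 1 for wildtype diquat, 220 and 0 for wildtype tBOOH, 291 and 80 for knockout diquat, 0 and 96 for knockout tBOOH (limma; 477 genes at an unadjusted p under 0.05, edgeR and DESeq2 0), 2436 and 0 for knockout against wildtype, and 446 and 0 for tBOOH against diquat. At 48 hpf they were 4 and 0, 16 and 0, 0 and 447 (limma; 319 genes at an unadjusted p under 0.05, edgeR 0, DESeq2 1), 19 and 2028, 242 and 0, and 3 and 0, in the same order. At 96 hpf they were 28 and 0, 263 and 0, 36 and 33, 857 and 0, 2635 and 0, and 192 and 0, and for the changes between stages 7712 and 24, and 3703 and 1. As many genes or more came from 10 of the 10 splits for knockout tBOOH at 2 hpf and knockout diquat at 48 hpf, from 2 for knockout tBOOH at 48 hpf, and from 1, the real split, for each other comparison. The splits with 447 and 2028 calls at 48 hpf point to a structure of the knockout samples, which parted water replicates 1 and 3, diquat replicate 2 and tBOOH replicate 1 from the rest by malat1 and mt-nd6. The overlaps of 8, 2 and 8 wildtype calls at 2, 48 and 96 hpf were reached by 4, 2 and 3 of 100 regroupings (highest 37, 4 and 114). The 196 list calls were reached by 2 of 100 (highest 204). Regrouping breaks every difference between the groups, so these shares bear on a difference of any kind. They do not test the sharing of calls or any single list. For the overlaps this test does not separate a shared response from the shared water libraries, and the 48 hpf overlap of 2 genes was 0 or 1 in 8 of the 9 fits with 1 library left out.

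Among wildtype diquat calls at 2 hpf, 7 genes also differed between the strains in water at 48 and 96 hpf, where independence gives 0.789 (53 called genes and 92 strain genes of 6177): cacna1ha, dnajb9b, ggcta, mchr1b, ttc14, zfpm2a and si:ch211-204c5.6. Argued against was a response to diquat common to both genotypes, since 1 of the 7 (14.3%) moved the same way in knockout diquat. Of the others mchr1b and ttc14 stood near 0 there (log2 -0.0062 and 0.0375). Over all tested genes the diquat responses of the genotypes at 2 hpf correlated at -0.00222, so this lack is not particular to the 7. Parental genotypes differing between pools may account for these genes, but the excess that marks them cannot test this. In 2 oxidant contrasts that do not use the wildtype diquat libraries no such excess was seen. Of these, wildtype tBOOH against water shared 4 where 2.96 were due, and knockout diquat against water 5 where 3.98 were due. Neither number excludes parents that differed for the wildtype diquat pools alone. Parental genotypes and a response to diquat in wildtype alone both stay open.

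Liver, intestine and exocrine pancreas genes were lower in knockout water at 96 hpf, with list medians of -2.37, -2.30 and -2.35. The authors' scaling was argued against, since the least negative of the 3 medians was -2.34 with TMM rescaling, and so was a state of the water libraries alone for liver and intestine, whose least negative median under the oxidants was -1.44. For exocrine pancreas that median was -0.58 and its call was lost with an estimated correlation (adjusted p = 0.401 in tBOOH), so such a state cannot be excluded. Slower development of the knockout pools may contribute: 725 other genes that rose at least 4-fold from 48 to 96 hpf in wildtype diquat had a knockout median of -0.33 (quartiles -1.67 and 0.51), which lies between the bounds set for and against it. The 25 genes that fell at least 4-fold had a median of 0.18, the direction a delay would give. Photoreceptor genes went the other way: they rose between these stages but were more often higher than lower in knockout water. Effects of the nfe2 mutation and of AB against AB and TL background cannot be told apart here, as genotype and background differed together.

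The mitochondrial gene mt-nd6 lies on the strand opposite to the other 12 mitochondrial mRNA genes, and few reads were counted (median 0.772 M of 25 M stated). Counting of reads on the opposite strand may lie behind both. It was raised by mt-nd6 itself, which was above the median of the other 12 in 54 of 54 libraries and highest in 44, so this level does not test it. Among the 100 highest genes 58.1% overlapped another annotated gene, against 40.9% for the further ranks up to 5000, a ratio of 1.42. This ratio left both that explanation and reads of overlapping genes undecided, since only 74% of the top 100 were matched to the reference, against 86.3% of the others. No biological explanation was tested. If reads were counted on the opposite strand, the value of every gene here would be a count of such reads, and for genes that overlap others it may include reads of those neighbours.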

How the results depend on the processing

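The fits without the libraries under 0.65 M reads and with library quality weights were chosen after the data were seen. Of the 652 calls of named genes, 376 kept their call in every fit with 1 library left out, 480 in every other alternative and 361 in both, and of 196 list calls 113, 45 and 45. Of the values of single genes and lists under the alternatives, 11060 kept direction and side of the threshold, 1912 kept direction and lost the threshold, 27 counts of calls shared by the genotypes moved by over 1.5 times and 1 value reversed: lens crystallins in 96 hpf knockout diquat against water, with adjusted p = 0.883 without 96 hpf knockout diquat replicate 3 (main value 1.31e-06, lowest 3.56e-15 without replicate 2). Counts of calls stayed within 1.5 times in 364 cases and moved further in 224. On simulated data at 96 hpf limma called 29% of genes raised or lowered 2-fold. Whether depth, the number of pools or their spread sets this share was not tested. Fewer libraries leave fewer degrees of freedom; the cause was not tested for any other movement below.

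With a pseudocount of 5 the counts that moved by over 1.5 times were at 2 hpf wildtype tBOOH 333, difference in tBOOH 16, at 48 hpf wildtype diquat 7, wildtype overlap 5, at 96 hpf wildtype diquat 51, difference in diquat 5, difference in tBOOH 58, wildtype overlap 13 and stage difference in diquat 70, stage difference in tBOOH 216. Without the low-value filter they were at 2 hpf wildtype tBOOH 69, knockout diquat 8, wildtype overlap 1 and at 48 hpf wildtype diquat 11, wildtype overlap 7. TMM rescaling moved at 2 hpf knockout diquat 70. With the replicate block (replicate number as a term) they were at 2 hpf wildtype tBOOH 459, knockout diquat 529, difference in diquat 121, difference in tBOOH 71, wildtype overlap 14 and at 48 hpf wildtype diquat 0, wildtype overlap 0. With only the compared groups in the fit they were at 2 hpf wildtype diquat 219, wildtype tBOOH 670, knockout diquat 0, difference in tBOOH 0, tBOOH against diquat 789, wildtype overlap 33, at 48 hpf wildtype diquat 30, wildtype tBOOH 50, knockout tBOOH 3, knockout against wildtype 73, tBOOH against diquat 56, wildtype overlap 19, at 96 hpf wildtype diquat 196, wildtype tBOOH 703, knockout diquat 2, difference in diquat 2, difference in tBOOH 99, tBOOH against diquat 682, wildtype overlap 67 and stage difference in diquat 113, stage difference in tBOOH 487. By edgeR quasi-likelihood they were at 2 hpf wildtype tBOOH 351, difference in tBOOH 3, at 96 hpf wildtype diquat 64, difference in diquat 4, difference in tBOOH 58, tBOOH against diquat 302, wildtype overlap 23 and at 48 hpf wildtype overlap 5. By DESeq2 they were at 2 hpf difference in tBOOH 69, wildtype overlap 4, at 48 hpf knockout diquat 1, knockout tBOOH 29, tBOOH against diquat 7, wildtype overlap 4, at 96 hpf wildtype diquat 56, difference in diquat 23, wildtype overlap 17 and stage difference in tBOOH 221. Without the libraries under 0.65 M reads they were at 48 hpf wildtype tBOOH 9, knockout against wildtype 111 and at 96 hpf wildtype diquat 61, wildtype tBOOH 482, knockout diquat 65, difference in diquat 15, difference in tBOOH 86, tBOOH against diquat 449, wildtype overlap 25. With library quality weights they were at 2 hpf wildtype diquat 268, wildtype tBOOH 1190, knockout diquat 550, knockout tBOOH 25, difference in diquat 194, difference in tBOOH 827, tBOOH against diquat 1173, wildtype overlap 65, at 48 hpf wildtype tBOOH 64, knockout diquat 286, knockout tBOOH 1742, knockout against wildtype 2406, difference in diquat 2, difference in tBOOH 400, tBOOH against diquat 13, wildtype overlap 5, at 96 hpf wildtype diquat 88, wildtype tBOOH 573, difference in diquat 28, difference in tBOOH 114, tBOOH against diquat 508, wildtype overlap 28 and stage difference in diquat 152, stage difference in tBOOH 597. Of 196 list calls, 48 held with an estimated correlation and 114 with fry.

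Leaving out 1 library at a time gave, as lowest and highest counts, at 2 hpf difference in diquat 35 to 151, difference in tBOOH 0 to 413, knockout diquat 0 to 689, knockout tBOOH 0 to 7, knockout against wildtype 1656 to 2624, wildtype overlap 0 to 10, wildtype diquat 30 to 57, tBOOH against diquat 110 to 718, wildtype tBOOH 0 to 640, at 48 hpf difference in diquat 0 to 0, difference in tBOOH 0 to 0, knockout diquat 0 to 1, knockout tBOOH 12 to 270, knockout against wildtype 73 to 808, wildtype overlap 0 to 2, wildtype diquat 0 to 3, tBOOH against diquat 1 to 3, wildtype tBOOH 6 to 11, at 96 hpf difference in diquat 0 to 74, difference in tBOOH 23 to 38, knockout diquat 21 to 177, knockout tBOOH 572 to 720, knockout against wildtype 1839 to 2206, wildtype overlap 3 to 7, wildtype diquat 4 to 26, tBOOH against diquat 70 to 123, wildtype tBOOH 121 to 195 and gene list tests 181 to 205, stage difference in diquat 31 to 43, stage difference in tBOOH 50 to 211, 2 to 48 hpf 7044 to 7150, 48 to 96 hpf 3004 to 3211.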

Other observations

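The correlations between genotypes, the counts of knockout against wildtype under the oxidants and the alas2 levels of single libraries were looked at after the data were seen; the changes between stages were planned.

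Wildtype water embryos changed in further gene groups between stages, by limma over all libraries. From 2 to 48 hpf unfolded protein and integrated stress response genes rose for 26 of 42 and fell for 4, hypoxia and glycolysis genes rose for 25 of 37 and fell for 3, ribosomal protein genes rose for 50 of 76, and glia genes rose for 12 of 21 and fell for 5. Adjusted over the list alone these counts were 26 and 4, 25 and 4, 50, and 12 and 5. From 48 to 96 hpf inflammation genes rose for 11 of 20 (median log2 1.304), heart genes for 8 of 10 (1.99), iron and heme genes for 9 of 16 with 1 fall (0.91) and mitochondrial transcripts for 6 of 13 (0.60). Adjusted over the list alone these were 11, 8, 10 and 1, and 7.

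Across all tested genes, log2 changes in wildtype and knockout correlated at 0.497 for tBOOH at 96 hpf and 0.151 at 48 hpf. For diquat the correlations were -0.00222, 0.0543 and -0.0418 at 2, 48 and 96 hpf, and for tBOOH at 2 hpf -0.0626. At 2 hpf 4 genes were called in both genotypes after diquat, each moving in opposite directions, and 0 in the same direction (limma; DESeq2 gave 1, the replicate block 9 and library quality weights 29, and leaving out knockout diquat replicate 1 or 2 gave 2 and knockout water replicate 3 gave 7). In knockout against wildtype pools at 96 hpf limma called 2635 genes in water, 1611 in diquat and 2370 in tBOOH. The erythroid gene alas2 lay between 0 and 5.69 in the 9 knockout libraries at 48 hpf and between 17.8 and 59.4 in the 9 wildtype libraries.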
